A study of Zea mays with 10 samples.

How the data were processed

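Nuclear RNA from B73 root tips was extracted, treated with DNase, depleted of ribosomal RNA and made into directional libraries with molecular identifiers, per the labels' protocols. Both groups came from tissue labelled with 5-ethynyl uridine, and the EU nascent group also went through a biotin-streptavidin pulldown. A pulldown from unlabelled tissue was not analysed here. Groups and replicate numbers 1 to 5 were taken from the sample labels, which call the replicates biological. The submitters' processing notes name Trimmomatic 0.36 and 0.39, STAR 2.7.10b, SAMtools, UMI-tools, deepTools and HTSeq, with no role or order. The labels and notes do not state the genome build, the annotation release or the strand setting of the counting. The gene identifiers are those of NCBI. Because the annotation release and the strand setting are not stated, values of overlapping and antisense genes are uncertain.

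The values deposited by the authors were taken to be expected counts, that is estimated counts of reads per gene with no normalization by the authors. This unit was read from the values and is not named in the labels. Most were whole within 1e-06, and the rest were multiples of 1 part in 12 within 0.0001, with every library summing to a whole number, so that reads shared between genes appear to have been divided by the authors. The series table and the 10 per-library files held the same values (0 differences). No row lacked a gene. Counts were rounded to whole numbers before testing. Of 48174 gene identifiers, 48127 (99.9%) matched a RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, which was used for names, biotypes and neighbours only, and 2909 had a name other than a locus number. Because the build of the files is unknown, no coordinates are given. Among tested genes, 5707 had a fractional count in at least 1 library.

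Fold changes are EU nascent over nuclear. The test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM scaling and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes are the absolute value divided by the square root of F. Levels are TMM-scaled counts per library total (CPM). Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01, for the 38 lists with at least 5 tested genes, and again with an estimated correlation and with fry. Values per library were compared by exact permutation, whose smallest two-sided p is 0.00794. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for these. The floor for a gene with no count was 3 counts and covers counting error only. The 95% intervals are bootstrap intervals over genes, which describe the spread between genes taken as independent.

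The tests, the alternatives, the lists and the rule for named genes were set before the data were examined. The lists had been planned on product descriptions, which the gene table does not give, so symbols and synonyms were matched instead, as planned for that case, and 39 of the 47 lists were taken over. The other 8 (MADS-box, cytokinin, glutathione transferases, benzoxazinoid synthesis, chromatin regulators, growth regulators, phosphate and potassium transporters, and transcribed pseudogenes) were added after the gene table was seen and before any fold change was. Lists of transposon-derived, proteasome, receptor-like kinase, ribosome biogenesis, F-box, NLR, shoot and leaf, organelle-encoded and RNA polymerase genes were not analysed here, nor were gene structure and single-exon genes. Named genes had an adjusted p under 0.05, a mean of at least 5 CPM and groups that did not overlap. Of these, the 12 with the highest and the 12 with the lowest log2 fold change among genes with a name were taken, with the most changed gene each way without one. For each called list, 2 members in its direction and 1 against it were added, and the 5 most abundant genes of each group. Genes named outside this rule are marked as such.

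Same-numbered libraries deviated together: the correlation across genes of their deviations from the group means was 0.20, 0.22, 0.18, 0.19 and 0.16 for numbers 1 to 5, and the highest with another number was 0.11. The labels give the numbers without saying what is shared, and the pairing was taken from these values, each above 0.1. The planned test had no block, and a fit with the number as a block was an alternative. Other alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters and leaving out each library. Added after the data were seen were thinned libraries, leaving out genes with fractional counts, numbers 1 and 3 or the 100 most abundant genes, pairing the numbers of genes detected, and leaving abundant members out of the shares of 2 classes.

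On simulated counts for 20846 genes with the real means and library sizes, the edgeR test of EU nascent against nuclear recovered 66% of 100 genes changed 1.5-fold and 92% of 100 changed 2-fold, and 6.94% of its calls were false. A planted list of 40 genes changed 1.25-fold was found by camera, and 2% of 200 random lists had a p under 0.05. The simulated genes were drawn independently and without paired replicate numbers, and few of them were changed. These rates therefore do not cover correlated genes and cannot check the preset correlation.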

Results

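Gene-level RNA abundance was measured in nuclei from maize root tips of the inbred line B73. Seedlings 3 days old were held in water for 1 h and then given 175 uM 5-ethynyl uridine for 1 h. This uridine analog enters RNA made during the labelling period and lets that RNA be biotinylated and captured on streptavidin. RNA came from nuclei of the last 1 mm of the root tip, which holds the meristem. One group of 5 libraries held the captured RNA and is called EU nascent. The other group of 5 libraries held total nuclear RNA from equally labelled tissue without the capture step and is called nuclear. The series asked how transcriptional activity measured by labelling compares with that read from total nuclear RNA. The EU nascent libraries held 2391209, 5770915, 2417533, 5686059 and 3997604 assigned counts for replicates 1 to 5. The nuclear libraries held 1323450, 5227257, 1702909, 20397606 and 4271254. Levels below are CPM, the counts of a gene scaled to the library. The p-values of edgeR and of the exact tests rest on the spread between these libraries. Those of camera compare a list with other genes and rest on the spread between genes. The table listed 48174 genes, of which 21048 had enough counts to be tested.

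The captured RNA differed from total nuclear RNA at many genes, mostly by small amounts. The transcription factor gene nac5, the transporter genes ysl12 and HAK21 and the lysine breakdown gene lkrsdh1 were among the named genes highest in EU nascent, and the chaperone gene HSP90-2, the glycine-rich protein genes grp1 and grp3 and 3 glutathione transferase genes were among the lowest. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4166 genes were higher and 4436 lower in EU nascent. A change of at least 2-fold was found for 384 of the higher and 728 of the lower genes. Changes under 1.5-fold made up 54.4% of the calls. The groups did not overlap for 5213 genes, or 24.8% of those tested, where chance gives 0.79%. Of the 8602 called genes, 7399 moved the same way in all 5 pairs of libraries with the same number. This is no separate support, since the genes were called on the same difference. For the 5059 called genes whose groups did not overlap, it follows by construction. Higher genes were 48.4% of the calls with the trimmed-mean scaling and 72.8% when library totals alone were used, which gave 7386 higher and 2765 lower genes. That scaling moved the median log2 fold change of all genes from 0.02 to 0.19, so every change given here is relative to the bulk of genes.

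Among the named genes, LIP (GeneID 542252), also listed as mas1 and coding for malate synthase of the glyoxylate cycle, had a log2 fold change of 1.84 ± 0.42 (SE, n = 5 per group). Its level was 13.6 ± 11.3 CPM in EU nascent and 3.32 ± 1.34 in nuclear (SD), with 32.9 in EU nascent replicate 1, and leaving out 1 library took its log2 fold change as low as 1.36. The NAC transcription factor gene nac5 (GeneID 103629850) had 1.82 ± 0.21, and with the replicate number as a block it stood above LIP (1.89 against 1.73). The yellow stripe-like gene ysl12 (GeneID 100505456), of a family that transports chelated metals, was higher by 1.44 ± 0.10 and reached 102 ± 7.3 CPM against 36.7 ± 5.65. ARGOS9 (GeneID 100273016) was higher by 1.39 ± 0.25 and the ethylene response factor gene ERF1 (GeneID 542184) by 1.28 ± 0.12. DIP1 (GeneID 732783) and ACR4 (GeneID 100285772) were both higher by 1.20, with SE 0.10 and 0.24. AUX10 (GeneID 100283620), of the auxin response list, was higher by 1.17 ± 0.19. The potassium transporter gene HAK21 (GeneID 103643618) and the G-box binding factor gene GBF1 (GeneID 542309) were both higher by 1.11, with SE 0.27 and 0.16. The methyl-binding domain gene mbd123 (GeneID 100383923) and the lysine breakdown gene lkrsdh1 (GeneID 541648) were both higher by 1.05, with SE 0.15 and 0.12. The largest edgeR adjusted p among these 12 genes and the 12 lowest was 0.00306.

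The lowest named gene was a methionine tRNA gene, TRNAM-CAU (GeneID 109940066), with a log2 fold change of -2.19 ± 0.32 (SE, n = 5 per group). MIR166b (GeneID 103318216), a precursor of the microRNA family that targets class III homeodomain-leucine zipper genes, had -1.86 ± 0.17. The chaperone gene HSP90-2 (GeneID 100384478) also had -1.86, with SE 0.14. The gene psat1 (GeneID 100284817) had -1.84 ± 0.11. The glycine-rich protein genes grp1 (GeneID 542725) and grp3 (GeneID 101027116) had -1.81 ± 0.14 and -1.80 ± 0.18, and grp1 fell from 3191 ± 739 CPM in nuclear to 908 ± 127 in EU nascent (SD). Glutathione transferase genes, which conjugate glutathione to reactive compounds, were 3 of the 12: gst5 (GeneID 542734) with -1.69 ± 0.22, GST25 (GeneID 541838) with -1.59 ± 0.21 and gst1 (GeneID 542366) with -1.51 ± 0.16. CSD4 (GeneID 100285240) had -1.67 ± 0.18, al1 (GeneID 101027139) -1.52 ± 0.17 and bZIP108 (GeneID 100191786) -1.46 ± 0.06. Fractional counts, which mark reads divided between genes, occurred at 10 of these 12 genes and at 1 of the 12 highest, mbd123, so their levels are uncertain. AUX10, MIR166b and GST25 each overlap another gene in the reference table, which adds to the uncertainty. Genes with fractional counts were 40.7% of those at least 2-fold lower, 19.5% of those at least 2-fold higher and 27.1% of those tested. A fraction in any 1 library set this mark, which depends on depth. Nuclear replicate 4, the deepest library, held 4136 genes with a fraction, against at most 2148 in any other library.

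**Figure D1:**
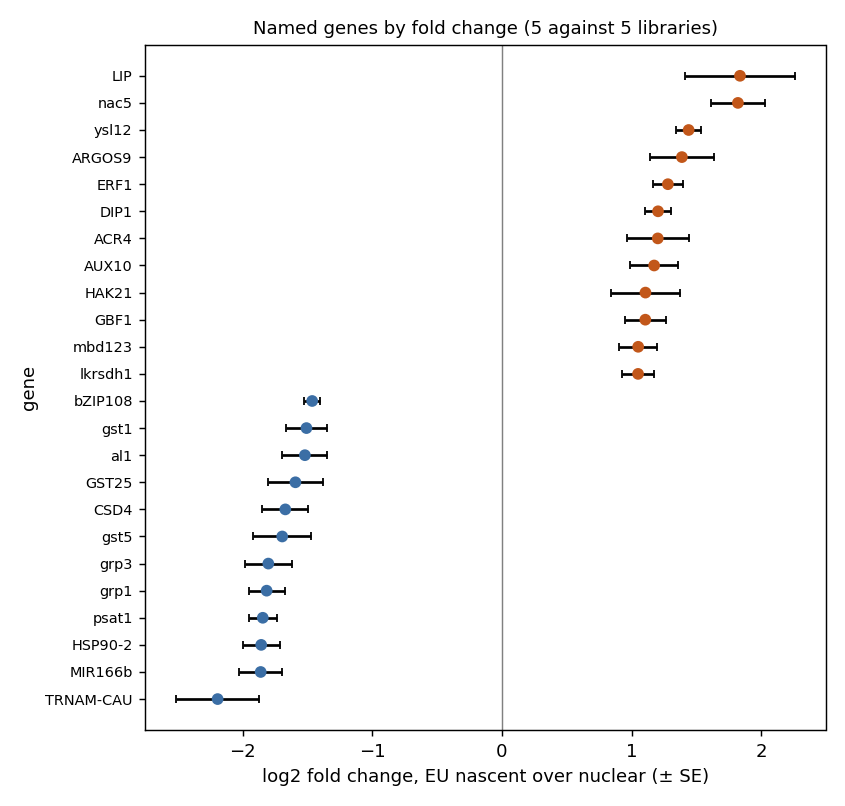
Log2 fold change of EU nascent over nuclear for the 12 highest and 12 lowest named genes, with bars giving the standard error from edgeR over 5 against 5 libraries. The higher genes lie between 1.05 and 1.84 and the lower ones between -2.19 and -1.46.

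Small nuclear RNA genes, whose products form the spliceosome and related particles, had the lowest median of the classes with at least 5 tested genes. Of 75 tested, 50 were lower, 5 higher and 20 did not pass the edgeR test, with a median log2 fold change of -1.52. Adjusted over the list alone, 53 were lower and 6 higher. LOC111590672 (-4.79 ± 0.39, SE) and LOC111590329 (-3.57 ± 0.56) were the members with the largest decreases that met the rule for named genes, and LOC111590674 went the other way (2.81 ± 0.38). LOC111590674 was also the most raised gene without a name other than a locus number. Small nucleolar RNA genes, which guide modification of ribosomal RNA, were more mixed, with 106 of 247 lower, 42 higher, 99 not past the test and a median of -0.32. Adjusted over the list alone, 110 were lower and 46 higher. LOC111590776, the most lowered gene without such a name, had no count in any EU nascent library against 68.0 ± 31.5 CPM in nuclear (SD, n = 5), at least 418-fold lower against a floor of 3 counts over the group. With that gene set at its bound the class median was -0.32 again. LOC111590776 overlaps a pseudogene in the reference table, which makes its counts uncertain. LOC111591031 had -4.88 ± 0.19, and LOC111590220, which lies over a protein-coding gene, had 1.86 ± 0.16. By camera, a test of a list against all other genes, both classes were lower, with adjusted p = 6.86e-09 for small nuclear and 8.67e-05 for small nucleolar RNA genes. Neither call held with an estimated correlation between genes (adjusted p = 0.677 for both, unadjusted p = 0.282 and 0.175). EU nascent replicate 1 stood apart in both classes, and without it the small nuclear RNA median was -2.18 (62 of 76 lower) and the small nucleolar one -0.25 (109 of 253 lower). LOC111590329 had -4.62 ± 0.45 without that library. Without genes that share reads, 16 small nucleolar genes were left with a median of -0.20, and the call was lost with so few (camera adjusted p = 0.596).

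Of the other biotypes, microRNA genes had 10 of 22 lower and 1 higher, with a median of -0.37 and a camera adjusted p of 0.0602. Long noncoding RNA genes had 216 of 731 higher and 128 lower, with a median of 0.13 and an adjusted p of 0.221. Transcribed pseudogenes had 124 of 498 higher and 100 lower (median 0.04, adjusted p = 0.569), and with library totals alone 192 higher and 64 lower (median 0.21). Other pseudogenes had 51 of 207 higher and 44 lower, with a median of 0.18, a mean of -0.03 and a camera direction of up (adjusted p = 0.509). Library totals alone gave 81 of them higher and 34 lower (median 0.35). Ribosomal RNA genes had 4 of 17 higher and 3 lower (median 0.70, adjusted p = 0.411) after the rRNA depletion named in the labels. Protein-coding genes had 3713 higher and 3981 lower of 19198 tested.

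**Figure D2:**
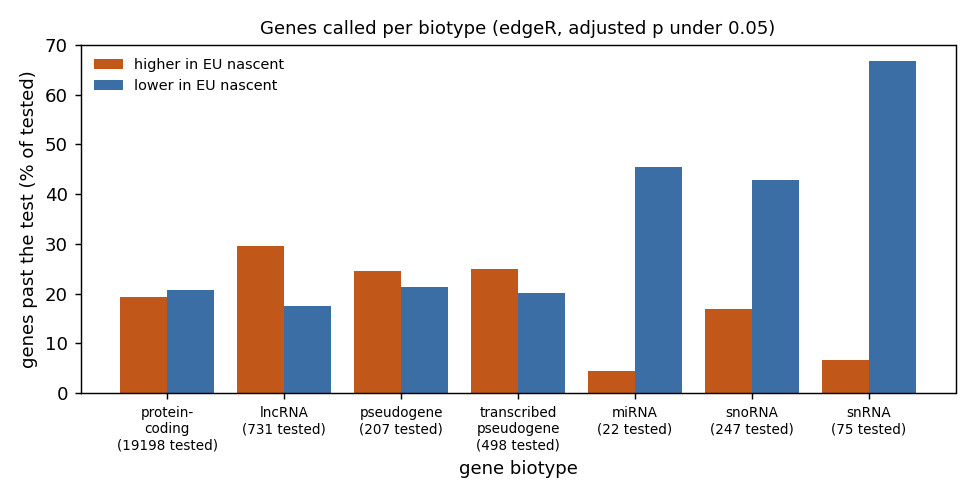
Percentage of tested genes called higher or lower in EU nascent per annotated biotype, by edgeR with adjusted p under 0.05. Lower calls are 66.7% of small nuclear and 42.9% of small nucleolar RNA genes, while higher calls exceed lower ones for long noncoding RNA genes (29.5% against 17.5%).

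The most abundant transcripts took a smaller share of EU nascent than of nuclear libraries. The long noncoding RNA gene LOC100384100 led both groups, with 9207 ± 880 CPM in EU nascent and 23200 ± 2563 in nuclear (SD, n = 5), a log2 fold change of -1.33 ± 0.08 (SE). bZIP108, annotated as a basic leucine zipper transcription factor gene, came next with 6296 ± 289 and 17360 ± 1304, and whether all reads counted for it come from its own transcript was not tested. The long noncoding RNA gene LOC103630547 had -1.21 ± 0.07, while LOC109941443 had -0.34 ± 0.10 and did not pass the test when library totals alone were used (-0.17, edgeR adjusted p = 0.162). The sucrose synthase gene ss2 (GeneID 542247), also listed as sus1, was among the 5 most abundant of EU nascent and went the other way, by 0.61 ± 0.10. The small nucleolar RNA gene LOC111590387 was among the 5 most abundant of nuclear, with 3483 ± 1118 CPM, and had -1.79 ± 0.56, or -3.18 ± 0.27 without EU nascent replicate 1. All of these except ss2 had fractional counts. The 100 most abundant genes of each library took 8.93% ± 0.35 of its counts in EU nascent and 13.4% ± 0.42 in nuclear (SD, n = 5, exact permutation p = 0.00794, adjusted 0.0218, two-sided). Together, LOC100384100 and bZIP108 held 1.55% of scaled counts in EU nascent and 4.06% in nuclear. Without these 2 genes the 100 most abundant took 7.38% ± 0.30 in EU nascent and 9.65% ± 0.43 in nuclear (exact permutation adjusted p = 0.0218). Median log2 fold change went from 0.10 over the 2162 genes under 5 CPM to -0.13 over the 2131 genes from 100 to 500 and -0.39 over the 81 genes above that, 50 of which were lower and 8 higher.

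Protein-coding genes took 89.7% ± 1.07 of counts in EU nascent and 85.4% ± 1.18 in nuclear (SD, n = 5). Long noncoding RNA genes took 4.95% ± 0.15 and 7.01% ± 0.33, and small nucleolar RNA genes 0.813% ± 0.41 and 2.06% ± 0.49. The long noncoding RNA difference rested largely on LOC100384100, LOC109941443 and LOC103630547, without which the class took 3.34% ± 0.067 and 3.94% ± 0.19. Each of these 3 class differences had an exact permutation p of 0.00794, the smallest that 5 against 5 libraries allow, and an adjusted p of 0.0218 over 11 classes, with all 5 pairs in the same direction. Small nuclear RNA genes took 0.540% ± 0.54 and 1.40% ± 0.51, lower in 5 of 5 pairs, which did not pass after adjustment (exact permutation p = 0.0317, adjusted 0.0582). Without EU nascent replicate 1, their EU nascent share was 0.299% ± 0.082 over the other 4 libraries and the difference passed (adjusted exact permutation p = 0.0175). Other pseudogenes took 0.504% ± 0.0070 and 0.537% ± 0.029 (adjusted exact permutation p = 0.0349), a call lost without EU nascent replicate 1, 2, 4 or 5 (adjusted p = 0.0728, 0.0728, 0.0873 and 0.0873). MicroRNA genes took 0.0344% and 0.0378%, lower in 5 of 5 pairs, which did not pass after adjustment (exact permutation p = 0.0397, adjusted 0.0624). The shares of ribosomal RNA genes (0.0227% against 0.0313%, exact permutation adjusted p = 0.466), transcribed pseudogenes (3.12% against 3.14%, 0.802), histones (0.127% against 0.129%, 0.802) and ribosomal proteins (0.252% against 0.271%, 0.36) did not pass the test. The microRNA difference passed without nuclear replicate 3 (adjusted p = 0.0437) and the ribosomal protein difference without nuclear replicate 1 (adjusted p = 0.0291), both by exact permutation. As differences within replicate numbers, no class could pass, since an exact sign-flip test of 5 pairs gives no p under 0.0625 (adjusted 0.0982 for the 5 classes called above).

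**Figure D3:**
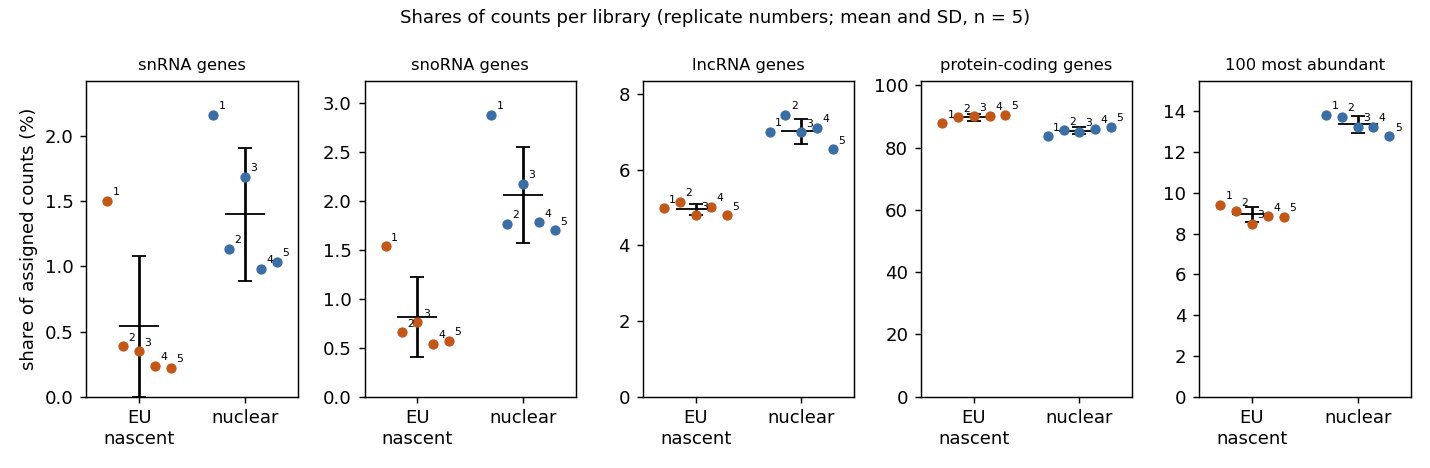
Share of assigned counts (%) per library for 4 gene biotypes and for the 100 most abundant genes of each library. Points are libraries with their replicate numbers, and lines give the mean and SD of 5 libraries; EU nascent replicate 1 lies above the other EU nascent libraries for small nuclear (1.5%) and small nucleolar (1.54%) RNA genes.

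Translation factor genes, which act in initiation and elongation of protein synthesis, were the called list with the fewest members. Of 13 tested, 8 were lower, 1 higher and 4 not past the edgeR test, with a median log2 fold change of -0.46 and the same counts when adjusted over the list alone. The elongation factor 1-alpha genes elfa3 (GeneID 542620, -1.29 ± 0.12, SE) and elfa2 (GeneID 100037748, -1.04 ± 0.14) had the largest decreases, and the initiation factor gene GOS2 (GeneID 541664) was higher by 0.82 ± 0.11. These 3 genes had fractional counts, and GOS2 also overlaps a protein-coding gene in the reference table. The list was called by camera (adjusted p = 0.0179) and not with an estimated correlation (adjusted p = 0.677, unadjusted p = 0.242), and the call was also lost with the 6 members that share no reads (camera adjusted p = 0.184), whose median was -0.36 (95% interval -0.84 to -0.12). Cytosolic ribosomal proteins had 10 of 37 lower and 3 higher, with a median of -0.15 that became 0.02 with library totals alone, and were not called as a list (camera adjusted p = 0.184).

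No other list was called by camera in the planned fit. In other settings microRNA genes, cytosolic ribosomal proteins and growth regulators were called at times, as given under the processing alternatives. The members given for the lists in the rest of the report were chosen after their values were seen. Of 11 histone genes, 5 were lower, all of them core histones, including his2b5 (-1.22 ± 0.12, SE) and H4C13 (-1.13 ± 0.10). The linker histone genes hon101 (0.90 ± 0.09) and his1a (0.42 ± 0.10) were the 2 higher ones. The other 4 did not pass the edgeR test. They were the linker histone genes hon110 (-0.04 ± 0.10) and H1 (0.03 ± 0.07), his2b2 (-0.16 ± 0.09) and cenH3 (-0.14 ± 0.15). The list's median was -0.16 (0.01 with library totals alone) and its camera adjusted p was 0.184. Heat shock proteins and chaperones had 14 of 33 lower and 5 higher, with hsp70-4 at -1.21 ± 0.11 and bip2 at -1.14 ± 0.14, both coding for HSP70-type chaperones, against HSF29 at 0.60 ± 0.20 (median -0.11, or 0.06 with library totals alone, camera adjusted p = 0.161). Tubulin and actin genes had 10 of 22 lower and 4 higher. The lower ones included the alpha-tubulin genes TUA2 (-1.12 ± 0.11) and tua6 (-0.93 ± 0.10), and the 4 higher ones were actin genes such as act2 (0.47 ± 0.15), with a camera adjusted p of 0.184. With library totals alone 5 were lower and 5 higher, and the median went from -0.28 to -0.11. Aquaporins had 8 of 16 lower and 2 higher (median -0.39, adjusted p = 0.355). Benzoxazinoid synthesis genes, which make defence compounds of grasses, had 4 of 8 lower and 1 higher, with Bx7 at -1.37 ± 0.16 and bx9 at -1.30 ± 0.13 (median -0.58, adjusted p = 0.161). Glutathione transferases had 6 of 19 lower and 3 higher, with GST26 at -2.08 ± 0.32 and gst41 at 0.92 ± 0.11 (median -0.11, or 0.06 with library totals alone, adjusted p = 0.569). Chromatin regulators had 28 of 88 lower and 14 higher (median -0.07, adjusted p = 0.184), and with library totals alone 22 lower and 28 higher (median 0.10).

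Lists with more higher than lower members included growth regulators and small plant-specific families, with 13 of 45 higher and 3 lower (median 0.22, camera adjusted p = 0.0941). GIF2 (1.02 ± 0.15, SE), CNR09 (1.02 ± 0.16) and ARGOS9 were among them. Phosphate, potassium and nitrate transporters had 8 of 20 higher, among them HAK23 (0.72 ± 0.10), and 2 lower, one of which was NAR2.1 at -1.20 ± 0.22, with an adjusted p of 0.161. The 3 ubiquitin genes tested were all higher, from 0.62 ± 0.08 for MUB14 to 0.84 ± 0.11 for MUB6. ERF and AP2 transcription factors had 9 of 25 higher and 5 lower (adjusted p = 0.355), and NAC factors 5 of 18 higher and 2 lower (adjusted p = 0.444), with NAC76 at 2.09 ± 0.35. WRKY factors had 5 of 14 higher and 3 lower (adjusted p = 0.509), bZIP factors 9 of 31 higher and 6 lower (0.509), and MYB factors 4 of 19 in each direction (0.615). With library totals alone 17 bZIP genes were higher and 5 lower, and 9 MYB genes were higher and 2 lower. The bHLH list had 5 of 29 higher and 3 lower (0.874), homeobox proteins 4 of 24 higher and 5 lower (0.903), and MADS-box proteins 0 of 6 higher and 1 lower (0.364), all by camera.

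Auxin response genes went both ways, with 12 of 39 lower and 7 higher (camera adjusted p = 0.355). AUX3 (-1.29 ± 0.09, SE) and AUX17 (-1.23 ± 0.13) were lower, and the auxin synthesis gene Yucca2 (0.90 ± 0.15) was higher. Cytokinin genes had 6 of 23 lower and 4 higher (adjusted p = 0.615), and jasmonate and wounding genes 4 of 33 lower and 3 higher, with a median of 0.02 and a camera direction of down (adjusted p = 0.996), and with library totals alone 3 were lower and 8 higher. TIFY30, of the jasmonate repressor family, had -1.33 ± 0.08. DNA replication genes had 5 of 16 lower and 2 higher (0.355), and mitosis and cytokinesis genes 9 of 28 lower and 4 higher (0.569). Cell wall genes had 8 of 25 lower and 7 higher (0.509), with the cellulose synthase gene CesA-1 (-0.60 ± 0.08) and the expansin gene expA3 (-1.48 ± 0.31) lower and the expansin gene expA4 (0.93 ± 0.21) higher. Glycolysis genes had 4 of 18 lower and 3 higher (0.753) and low oxygen genes 3 of 10 higher and 1 lower (0.505). Splicing factors had 3 of 13 higher and 2 lower (0.509), photosynthesis genes 2 of 7 in each direction (0.874), cytochrome P450s 1 of 7 in each direction (0.747) and pentatricopeptide repeat proteins 2 of 7 lower and 0 higher (0.569). These are camera adjusted p values. With library totals alone the medians of the auxin, cytokinin, DNA replication, mitosis, cell wall, glycolysis, photosynthesis, pentatricopeptide repeat, bHLH and homeobox lists changed from negative to positive, as did those of the C2H2 and peroxidase genes. With that scaling the counts also turned: 9 mitosis genes were higher and 5 lower, 9 cell wall genes higher and 5 lower, 6 glycolysis genes higher and 2 lower, 7 homeobox genes higher and 3 lower, 5 cytokinin genes higher and 3 lower, and 3 DNA replication genes higher and 2 lower. Splicing factors then had 8 higher and 0 lower, and auxin genes 9 higher and 10 lower.

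Markers of cell types and tissues were few among the tested genes and were given no list test. The root cap gene RCP1 did not pass the edgeR test (-0.08 ± 0.18, SE) and agp, also listed as RCP2, was higher (0.81 ± 0.18). The root hair genes rth3 (0.34 ± 0.09) and RHL2 (0.36 ± 0.13) were higher. The laccase gene LAC1, a marker of lignifying vascular tissue, was higher by 1.82 ± 0.30. SCR, a regulator of the stem cell niche and ground tissue, did not pass (-0.27 ± 0.14). Of seed genes, dehydrin3 was lower (-1.07 ± 0.13) and FL1 did not pass (-0.14 ± 0.33). The peroxidase gene PER1 did not pass (-0.08 ± 0.16), and of 4 C2H2 zinc finger genes IDDveg9 was lower (-0.86 ± 0.10), znf was higher (0.36 ± 0.11) and 2 did not pass.

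The profiles of the groups were close across genes. Group means of log2 CPM correlated with Pearson's r = 0.946 and Spearman's rho = 0.956 over 21048 genes, which are not independent replicates. Pairs of libraries within a group correlated with a mean r of 0.965 (0.939 to 0.988), and pairs across groups with 0.919 (0.881 to 0.940). The difference of 0.046 was the largest of all assignments of libraries to groups (one-sided exact permutation p = 0.00794, the smallest possible). These assignments ignore the pairing of replicate numbers, within which profile agreement was not tested. At least 10 counts were found for 20888 ± 1149 genes in EU nascent and 20448 ± 3184 in nuclear (SD, n = 5), a difference that was not detectable at these unequal depths (exact permutation p = 0.794, two-sided). After thinning every library to the smallest total, the numbers were 17572 ± 51.2 and 16903 ± 31.9, higher in EU nascent in 5 of 5 pairs (exact permutation p = 0.00794). As differences within replicate numbers this did not pass (exact sign-flip p = 0.0625, the smallest for 5 pairs). The biological coefficient of variation was 13% in EU nascent and 10.0% in nuclear. Without EU nascent replicate 1 it was 9.14% in EU nascent, so the order of the groups rested on that library.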

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

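Values per library were tested for a library far from the other 4 of its group, over total counts, genes detected, 11 class shares and 38 named genes. Of 102 such groups 10 stood out, and chance gives about 1 in 20. The tests of other splits and of EU nascent replicate 1, and those of the scaling and without genes that share reads, were chosen only after the results were seen.

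EU nascent replicate 1 held 1.5% of its counts in small nuclear RNA genes against a median of 0.293% in the other EU nascent libraries, 1.54% in small nucleolar RNA genes against 0.616%, and 87.9% in protein-coding genes against 90.2%. The genes LOC111590329 (58.9 against 6.85 CPM) and LOC111590387 (3534 against 380) were high in it, and ss2 was low (2500 against 3487). Over 102 small nuclear and nucleolar RNA genes with a mean of at least 20 CPM that were at least 2-fold lower in EU nascent without this library, it lay a median of 0.448 of the way from the other EU nascent libraries to the nuclear level (95% interval 0.299 to 0.641). Carry-over of unlabelled nuclear RNA would move other depleted genes alike, but over 281 of them the fraction was 0.0701 (0.047 to 0.102). A few genes held a part of the excess and not the whole: the 5 with the most held 37.2% of it over all 322 tested genes of both classes (23.8 to 48.8), 182 of which were higher in this library than the mean of the other 4. Nuclear replicate 1 was also raised, by a median of 0.64 (0.51 to 0.78), less than a full account of the 2.01 in EU nascent replicate 1 needs, so nuclei richer in these RNAs may hold part of it. Small nuclear RNA genes took 1.69% of counts in nuclear replicate 3, beside 2.16% in nuclear replicate 1. Their share in EU nascent replicate 3 was nonetheless 0.349%. A difference in how short RNA passed through this pulldown stays open, and no biological explanation was tested.

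Small nuclear RNA genes were lower in EU nascent with a median log2 fold change of -1.52. The 33 genes with no fractional count had a median of -1.37 (95% interval -1.72 to -0.94), with 22 lower and 3 higher. Divided reads that leave a fraction are therefore not the whole cause. Parts that sum to a whole number leave none, so sharing between near-identical copies is not excluded for these genes. Camera called the 33 genes at the preset correlation (adjusted p = 0.00017), and the estimated correlation was not run for them. The full list was not called at the estimated correlation (camera adjusted p = 0.677). For small nucleolar RNA genes shared reads cannot be told apart from a real difference. There, 16 genes had no fractional count, with a median of -0.20 (-0.67 to 0.84) beside -0.32 over all 247. The camera call ended with so few genes (adjusted p = 0.596). The criterion was made stricter after these values were seen: at first a lost call with an interval that includes 0 was enough to count for shared reads, and by it they would have accounted for the pattern. Stable RNA made before the labelling and poor recovery of short RNA in the pulldown were not tested and stay open for both classes.

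Translation factor genes had a median of -0.46. Of 10000 random lists matched on mean expression, the median was -0.10 and 95% lay from -0.36 to 0.13. The list's median lies below that range. The range takes the genes as independent, and the list was examined because camera had called it low. The measure set in advance was the list's percentile, computed as 11.2, which by its rule counts for lower values of abundant genes. This percentile does not match the list's median, which lies below the range. Neither is used to decide, and lower values of abundant genes as the cause stay open. A scaling set by the most abundant genes moves all genes together, so no change of scaling could alter the distance of the list from other genes. Comparing scalings therefore cannot test this explanation. Library totals alone moved the median of all genes from 0.02 to 0.19. The list's median stayed below it by the same amount as in the planned fit (difference -0.47, 95% interval -0.79 to -0.25). The camera call with library totals alone (adjusted p = 0.0104) adds nothing here, since camera compares the list with other genes. In the planned fit the call was lost at the estimated correlation (camera adjusted p = 0.677). Without genes that share reads, 6 members were left with a median of -0.36 (-0.84 to -0.12) and an adjusted p of 0.184, so that shared reads cannot be told apart with so few genes.

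Nuclear replicate 4 had 20397606 counts against a median of 2987082 in the other nuclear libraries. EU nascent replicate 3 had 0.0501% of its counts in ribosomal RNA genes against 0.0160%. In it LOC111590674 reached 19.7 CPM against 9.14. In nuclear replicate 2 ERF1 reached 37.3 CPM against 24.8.

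The number of called genes was compared with 100 splits of the 10 libraries into 5 and 5. Only 1 of them, the real one, called as many as 8602 genes, and the highest other split called 130. Every other split puts libraries of both groups on each side, so a real difference widens the spread and lowers its calls. With 126 possible splits, the comparison cannot say how unlikely chance is beyond 1 in 100. Of the splits drawn, 14 part all 5 pairs of same-numbered libraries, the real one included, and the others of these called 0 genes by edgeR.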

How the results depend on the processing

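The alternatives that thin libraries, leave out genes with shared reads, leave out numbers 1 and 3, leave out the 100 most abundant genes pair the numbers of genes detected or leave abundant members out of 2 shares were chosen after the data were seen. The named genes were checked with library totals alone, DESeq2, the replicate block and leaving out 1 library. Of these 152 alternative values, 151 kept direction and call, and LOC109941443 lost its call with library totals alone. Most named genes were chosen for large changes, so this says little about other genes. Of all genes called in the planned fit, 80.6% kept call and direction with library totals alone. After thinning, which left fewer genes to test, 60% did. With library totals alone 7386 genes were higher and 2765 lower, 733 of the higher by at least 2-fold. Without a count filter 617 genes were at least 2-fold higher and 1430 lower. Thinned to the smallest total, 2498 were higher and 2885 lower, where depth limits the calls. Without genes that share reads 453 were at least 2-fold lower among fewer genes tested. Lists called by camera numbered 3, but 1 without genes that share reads, 0 with an estimated correlation and 17 by fry, which does not compare a list with other genes. They numbered 4 where microRNA genes (library totals alone, without EU nascent replicate 2, without nuclear replicate 5), cytosolic ribosomal proteins (without nuclear replicate 1, without numbers 1 and 3) or growth regulators (thinned) were added. Leaving out 1 library gave 3406 to 4636 higher and 3898 to 4633 lower genes. DESeq2 gave 3922 and 4247, and limma-voom 4553 and 4851. With the replicate block there were 5099 higher and 5347 lower genes and the same 3 lists; among the gene counts, lists, named genes, shares and genes detected, for which it was run, the pairing changed the calls of 5 shares and of the genes detected after thinning (669, exact sign-flip p = 0.0625). It was not run for profile agreement and spread. For the shares, differences within numbers were 4.27 points for protein-coding, -2.07 for long noncoding RNA, -1.25 for small nucleolar RNA, -0.0334 for pseudogenes and -4.42 for the 100 most abundant genes, with an adjusted sign-flip p of 0.0982; the smallest unadjusted p of 5 pairs is 0.0625. Without abundant members the differences were -0.596 points for long noncoding RNA and -2.27 for the 100 most abundant genes. Leaving out 1 library, the small nuclear RNA share difference ranged from -1.10 to -0.671 points, microRNA from -0.0041 to -0.00241, pseudogenes from -0.0401 to -0.0216 and ribosomal proteins from -0.0325 to -0.00917. Ribosomal RNA ranged from -0.0154 to -0.00255. Transcribed pseudogenes (-0.0544 to 0.0247) and histones (-0.0059 to 0.00279) changed sign. Correlation of the group means was 0.983 with no count filter. The number of genes detected differed by 439.8 as sequenced (exact sign-flip p = 0.688 within numbers) and by 669 after thinning. As sequenced it ranged from -448.2 without nuclear replicate 1 to 1557.3 without nuclear replicate 4, and was -557.4 at a minimum of 1 count. The excess of the EU nascent coefficient of variation over nuclear, 2.97 points, reversed to -0.90 without EU nascent replicate 1 and was at most 4.43. Where no construction is named, the cause was not tested. Trends of GC content and length, alone or with the block, gene structure and organelle-encoded genes were not run, since no sequence or transcript annotation was used here, and the second copy of the counts was identical.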

Other observations

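The test of neighbouring genes was set before its result was seen, and the test of transcription factors as 1 list was chosen after the single lists were seen. Small nucleolar RNA genes went both ways, and many of them lie within longer genes. In the reference gene table, 166 of the 247 tested overlap a protein-coding or long noncoding RNA gene. Of these, 49 were lower and 40 higher in EU nascent, with a mean log2 fold change of -0.14 and a median of -0.06. Of the 81 that overlap neither type, 57 were lower and 2 higher, with a mean of -1.40 and a median of -1.12. The means differed by 1.25 (95% interval 0.90 to 1.66, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). This p and interval take the genes as independent, while 231 of the 247 share reads with other genes, so both overstate the certainty. Of the 16 that share none, 11 overlapping genes had a mean of 0.14 and 5 others -2.96. The latter mean includes LOC111590776, with no count in EU nascent, at its fitted value of -11.35 and not at its bound. This 1 gene weighs heavily on a mean of 5, and it also enters the mean of the 81. It overlaps a pseudogene, a type that the comparison did not consider. A candidate explanation is that counts at the overlapping genes include reads of the longer gene's unspliced transcript, while those at the others come from the mature small RNA. The table may follow another annotation than the counts, and strand was not considered.

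Several transcription factor lists had more higher than lower members. As 1 list of 170 tested genes from 9 families, 42 were higher and 30 lower, and the median log2 fold change was 0.07 (95% interval -0.02 to 0.16) beside 0.02 over all genes. Camera did not place the list above other genes (p = 0.361, and p = 0.328 with an estimated correlation), so whether these genes lean higher as a group stays open.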
